A study of Marchantia polymorpha subsp. ruderalis with 2 samples.

How the data were processed

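The libraries were made from DNA of sperm of the liverwort Marchantia polymorpha, 1 from wild type and 1 from the Mpdn4mt1-1 mutant, which the labels call a double knockout. Per the labels' protocols, the DNA was copied by whole genome amplification before library preparation and both amplified libraries shared a Sequel II SMRT Cell run in circular consensus mode, with no spike-in of modified DNA. SMRT sequencing reads a DNA molecule repeatedly and infers base modifications from the polymerase's kinetics. Amplification makes copies from unmodified nucleotides, so the calls in these libraries measure the background of the callers plus any template that escaped copying. With 1 library per genotype there is no replicate spread, and no test of genotype was made.

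The authors' deposited files give values in windows of 100 bp. For N4-methylcytosine (4mC) there is a file per library for each of the contexts CG, CHG and CHH, where H is A, C or T. The deposited score is the mean 4mC fraction over all cytosines of the context in the window, with cytosines that were not called set to 0, as judged from the values. A further field gives the number of called cytosines and the number of all cytosines of the context on both strands. These are numbers of sites, not of reads. The number of all cytosines was identical in both libraries in every window, so a cytosine without reads counted as uncalled, and the read depth behind a 4mC call is unknown. For 5-methylcytosine (5mC) in CG the deposited score is a fraction, the modified read calls over all read calls in the window, and a further field gives both counts and the number of CGs with calls. The lowest mean number of read calls per CG in a listed window was 4. The aligner, the modification callers and the genome build are not given in the sources used here. The files name chromosomes 1 to 8 and V and 435 unplaced scaffolds. The sex chromosome V is that of males. No 4mC was called on the scaffolds in either library (0 of 316357 CG, 253888 CHG and 781346 CHH cytosines), so the scaffolds were treated as not assessed for 4mC and left out of the comparisons.

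The gene table used for names belongs to another assembly, MpTak2_v7.1, and was not matched to the files' coordinates. Levels by annotated feature and by gene list, both planned, were therefore not computed, the targeted gene was not analysed here, and sites are named by position without annotation. Native libraries were not analysed here.

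The 4mC level was computed as called cytosines over all cytosines, and the 5mC level as modified read calls over all read calls, both pooled over the chromosomes. Exact Clopper-Pearson 95% intervals were computed for each level. They cover counting error only, and read calls from amplified DNA are not independent molecules. A bootstrap over 219 blocks of 1 Mb (1000 draws) gave intervals for each level and for the difference of mutant minus wild type. These cover position along the genome, not plants. Window tests used windows with at least 10 calls in both libraries, where a call is a cytosine for 4mC and a read call for 5mC. A window above background passed a one-sided exact binomial test against the level of its library at a Benjamini-Hochberg adjusted p of 0.05. Overlap between the libraries was set against 100 circular shifts along each chromosome and against the overlap expected if libraries were independent within strata of GC content and number of calls. Differing windows passed a two-sided Fisher exact test at the same threshold, which compares the 2 libraries and not the genotypes. Read depth was taken from the 5mC files as read calls per CG. Levels at matched depth weighted each depth bin, or each bin of depth and GC content in steps of 5%, alike in both libraries. Windows were binned by the depth in their own library, so a bin could hold different places in each.

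Named sites followed a rule set before the data were examined. For each of the 4 measurements it took the 6 regions with the highest mean level among those above background in both libraries, with at least 20 calls in each and adjacent windows merged. It also took the 3 regions in each direction with the largest difference past the Fisher test.

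After the data were examined, the number of CGs with 5mC calls in a window was set against the number in the reference, which is the number of CG cytosines over both strands divided by the strands. A window at a depth of at least 8 in both libraries was called mismatched when the numbers differed by over 0.5. Blocks were classed by a difference of at least 10 mismatched windows per 1000 between the libraries. A run without calls was at least 50 windows with calls in one library and none in the other, among windows holding a CG. Windows without calls in either library neither ended a run nor counted towards its windows, but their cytosines entered its 4mC level. Runs of 5.9 to 6.1 kb without any 4mC call were used as templates to search the genome for sequence with the same profile of CG, CHG and CHH numbers over 58 windows, at a Pearson r of at least 0.5 in either orientation.

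The tests were tested on simulated counts with the real numbers of calls per window. Of 100 windows raised to 50% in both libraries, 89 were recovered for CG, 90 for CHG, 98 for CHH and 98 for 5mC, with 0 false calls. At 20% the recovered numbers were 11, 6, 32 and 53. The simulated background was a single level per library, while the real level varied with base composition and, for 5mC, read depth. The 0 false calls therefore give no rate of false calls in the real windows. Of 100 windows raised to 50% in a single library, the Fisher test recovered 0 for CG, 0 for CHG, 6 for CHH and 62 for 5mC. It therefore has little power for 4mC. When 5mC calls were drawn from read depth alone, the pooled difference was 0.446 points and the difference at matched depth 0.00448 points (0.000560 to 0.00780). Of 20 blocks raised by 30 mismatched windows per 1000, 20 were classed as raised, and 11 of the 199 other blocks were classed as differing. Circular shifts gave p under 0.05 for 3 of 100 pairs of unrelated smooth series and for 100 of 100 related pairs. Of 100 repeat copies planted among windows in shuffled order 100 were found, with 0 places found elsewhere. Shuffling removes local composition, so this gives no rate of false matches in the real genome. Alternatives covered the minimum number of calls, the weighting of windows, the sequences included, the threshold, the background level, the test and thinning, and matching on depth and GC content was added after the data were examined. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.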

Results

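Base modification calls were compared between amplified sperm DNA of wild-type Marchantia polymorpha and of the Mpdn4mt1-1 mutant, named for a DNA N4-cytosine methyltransferase. Amplified DNA serves as the background against which modification in native DNA is read. There was 1 library per genotype, so no value has a replicate spread, every difference is one between 2 libraries, and exact intervals on single levels cover counting error only. Positions are those of the deposited files, whose genome build is not given in the sources used here, and the targeted gene was not analysed here. The wild-type library held 172823339 read calls for 5mC over 8045875 CGs on the chromosomes, and the mutant library 81757976 over 7593965. The mean depth was 21.5 read calls per CG in wild type and 10.8 in the mutant. For 4mC, 16633180 CG, 15761065 CHG and 58867329 CHH cytosines were assessed in each library.

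4mC calls were rare in both libraries and rarest in CG. In wild type 0.423% of CG cytosines were called (exact 95% interval 0.420 to 0.426%), 0.697% of CHG cytosines (0.692 to 0.701%) and 1.11% of CHH cytosines (1.10 to 1.11%). The mutant levels were 0.430% (0.427 to 0.434%), 0.611% (0.607 to 0.615%) and 1.05% (1.04 to 1.05%). The order CG, CHG, CHH was therefore the same in the wild-type and the mutant library. CHG was lower in the mutant by a difference of -0.0856 percentage points (block interval -0.0947 to -0.0772) and CHH by -0.0613 points (-0.0710 to -0.0527). The interval for CG, 0.00720 points (-0.000854 to 0.0150), included 0. A called cytosine had a higher 4mC fraction in the mutant, with medians in windows with a single call of 65.7% against 59% in CG, 50.2% against 44.9% in CHG and 51.3% against 45.9% in CHH. On the deposited mean fraction the CHH difference had the opposite sign, 0.0274 points (0.0223 to 0.0322). In windows matched on depth and GC content the differences were -0.0374 points in CG (-0.0481 to -0.0265), -0.0379 in CHG (-0.0512 to -0.0263) and 0.0251 in CHH (0.0125 to 0.0380).

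**Figure D1:**
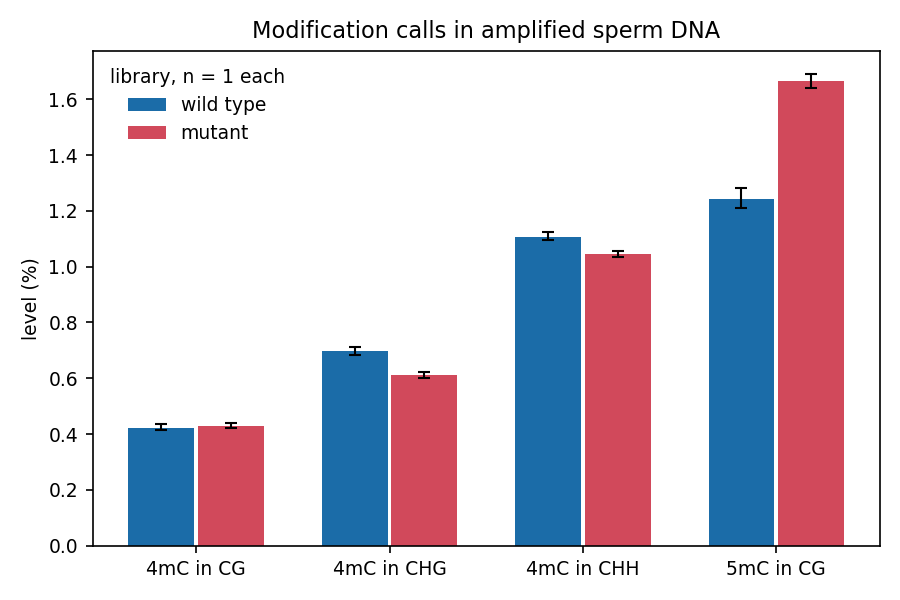
Level of each modification (%, vertical axis) in the wild-type and mutant libraries (1 each), with block bootstrap 95% intervals as error bars. 4mC is lowest in CG and highest in CHH in both libraries, and 5mC is 1.24% in wild type and 1.67% in the mutant.

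Native sperm 4mC was expected to lie in CG and CHG more than in CHH, so the ratios of these contexts were compared as a measure of template that escaped amplification. CG reached 0.382 of the CHH level in wild type (0.376 to 0.388) and 0.411 in the mutant (0.405 to 0.418). CHG reached 0.629 of the CHH level in wild type (0.623 to 0.635) and 0.584 in the mutant (0.579 to 0.590). The CG ratio was thus higher in the mutant by 0.0293 (0.0234 to 0.0352), and the CHG ratio differed by -0.0450 (-0.0502 to -0.0397). In windows matched on depth and GC content the CG ratio had the opposite order, 0.421 in wild type and 0.378 in the mutant, a difference of -0.0429 (-0.0503 to -0.0348).

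5mC calls in CG were more frequent in the mutant library. The level was 1.67% in the mutant (1.66 to 1.67%, 1361387 modified read calls) and 1.24% in wild type (1.24 to 1.25%, 2150561 modified read calls). The difference was 0.421 points, with a block interval of 0.395 to 0.444. The level depended on read depth with nearly the same curve in both libraries. At 4 read calls per CG it was 5.72% in wild type and 5.48% in the mutant, at 10 it was 1.56% and 1.45%, and at 20 it was 0.690% and 0.719%. It rose again to 2.38% and 2.44% at 35 to 39 read calls. In windows matched on depth the difference was -0.0431 points (-0.0582 to -0.0295). Without the windows above background it was -0.0741 points, but this filter acts on the level itself, and more of the windows it removed were above background in the mutant (83301) than in wild type (49625). In windows holding a single CG at a depth of 40, 93.8% in wild type and 94.2% in the mutant had a modified call, but only 2.04% and 3.85% had at least 2, in 1226 and 52 windows. Independent read calls would not give so many windows with a modified call and so few with at least 2. The exact intervals and window tests for 5mC assume independent read calls and are therefore not calibrated.

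**Figure D2:**
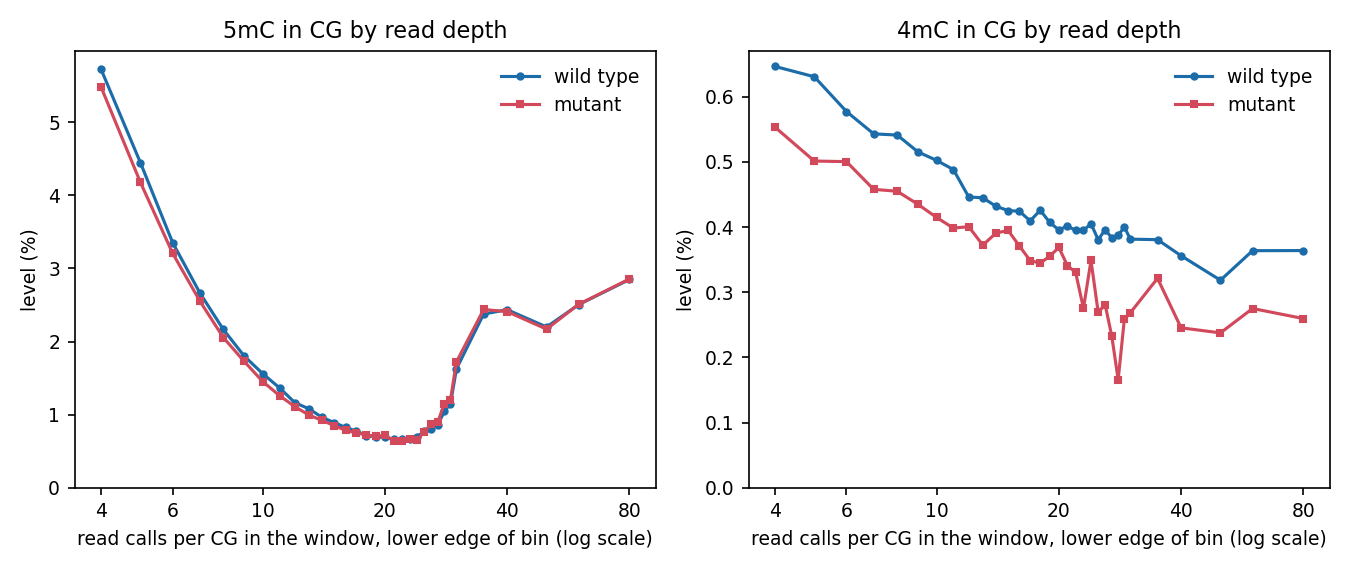
Level of 5mC in CG (left) and 4mC in CG (right), in %, against the read calls per CG of the window in the same library (log axis), with 1 point per depth bin in the wild-type and mutant libraries. The 5mC curves nearly coincide, while 4mC in CG falls with depth and lies lower in the mutant at each plotted depth.

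4mC background followed base composition. In windows of 45 to 50% GC the CHH level was 0.840% in wild type and 0.872% in the mutant. It was 1.70% and 1.46% in windows under 25% GC, and 3.14% and 2.13% in windows of at least 65% GC. CG and CHG had their highest levels in the same GC-rich windows, with 0.95% and 0.740% in CG and 1.83% and 1.23% in CHG.

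The sex chromosome V stood apart from the autosomes. Its 4mC level in CG was 0.347% in wild type (0.332 to 0.361%) and 0.359% in the mutant (0.345 to 0.374%), against 0.426% and 0.433% on the autosomes. Its 5mC level was 1.75% in wild type and 2.01% in the mutant, against 1.22% and 1.65% on the autosomes, at a depth of 24.9 and 13.1 read calls per CG. The wild-type excess lay mainly at 6 to 8 Mb of V, where the blocks had 2.16% and 2.65%, while the other V blocks had 1.17% to 1.46%. In these blocks, chosen after their values were seen, which were not matched on depth, the mutant was lower by differences of -0.231 and -0.290 points. Among the autosomes chromosome 3 had the highest 4mC level in CG, 0.50% in wild type and 0.493% in the mutant. On chromosome 8 the CG level was 0.439% in wild type (0.429 to 0.449%) and 0.397% in the mutant (0.388 to 0.407%). Chromosome 4 had the opposite order, 0.398% (0.390 to 0.407%) and 0.432% (0.423 to 0.441%).

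In some segments, up to several Mb long, the number of CGs with 5mC calls departed from the number in the reference in more windows of 1 library than of the other. This is an indirect measure, and no sequence was examined. A CG that lacked calls in a covered window also counted towards a mismatch. Of 219 blocks, 183 differed by less than 10 mismatched windows per 1000, 21 had more in the mutant and 15 more in wild type. The blocks with more in the mutant lay at 5 to 8 and 9 to 10 Mb of chromosome 1, 18 to 25 Mb of chromosome 2 and 0 to 10 Mb of chromosome 4. Those with more in wild type lay at 24 to 26 Mb of chromosome 4, 0 to 3 and 4 to 5 Mb of chromosome 7, and 0 to 2 and 14 to 21 Mb of chromosome 8. At 0 to 10 Mb of chromosome 4 a mean of 130 windows per 1000 was mismatched in the mutant against 83.9 in wild type, and at 14 to 21 Mb of chromosome 8 the means were 80 and 145. In the blocks with more mismatches in the mutant the CG level was 0.469% in the mutant and 0.382% in wild type, a difference of 0.0864 points (0.0596 to 0.114) that was 0.0401 points (0.00973 to 0.0720) in windows matched on depth and GC content. The CHG difference there, 0.00842 points (-0.0162 to 0.0342), included 0, and was 0.0894 points (0.0574 to 0.122) in matched windows. In the blocks with more mismatches in wild type the CG level was 0.409% in the mutant and 0.502% in wild type, a difference of -0.0936 points (-0.147 to -0.0428), and -0.142 points (-0.209 to -0.0806) in matched windows. Across the 219 blocks, which are not independent replicates, the difference in mismatches correlated with the difference in 4mC at a Pearson r of 0.685 in CG, 0.677 in CHG and 0.745 in CHH. Spearman rho was 0.295, 0.407 and 0.381, with p = 0.00913, 0.00457 and 0.00457 from circular shifts of the blocks, of which 0.00457 is the smallest they can give. Adjusted over the 6 relations computed these were 0.0137, 0.00913 and 0.00913. Without the 2 blocks farthest from the median r was 0.607, 0.604 and 0.692. The 5mC difference did not follow the mismatches detectably (r = 0.0671, rho = 0.0560, circular-shift p = 0.397, adjusted 0.397).

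**Figure D3:**
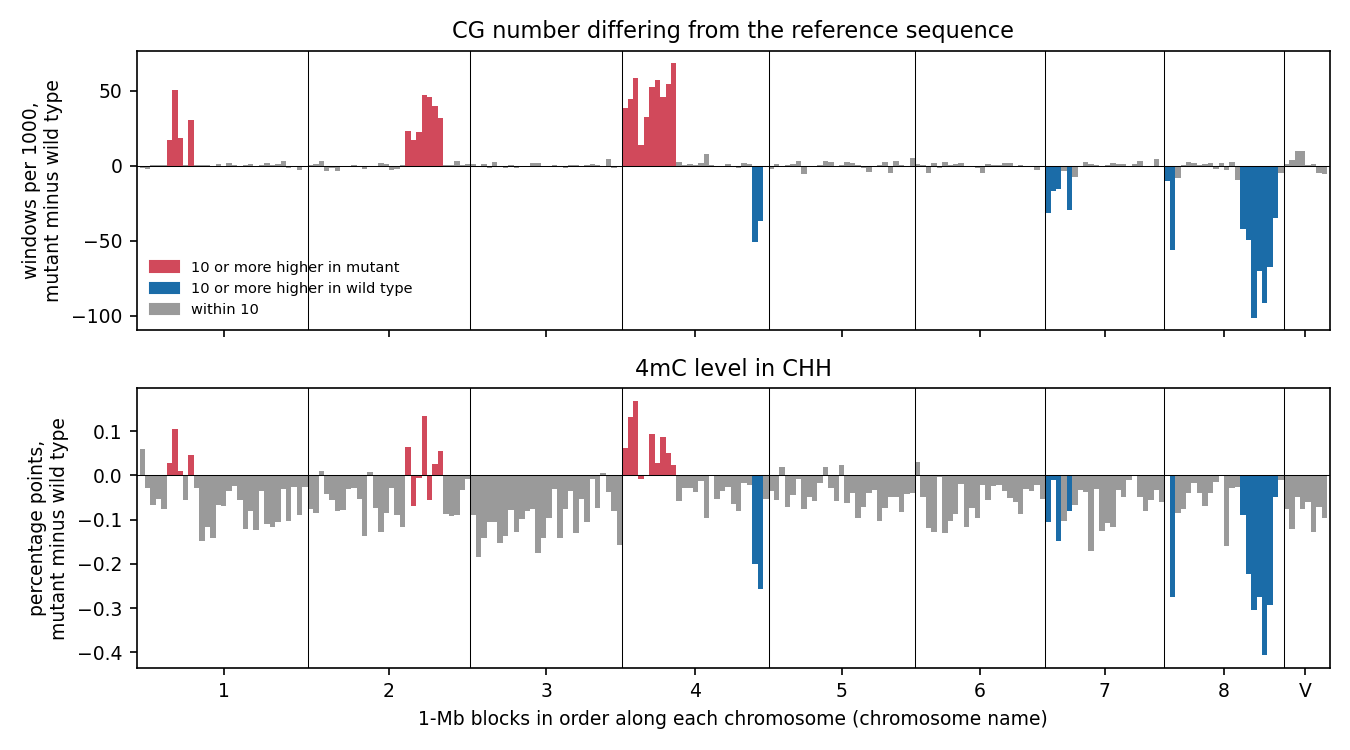
Difference of mutant minus wild type in blocks of 1 Mb along the chromosomes, in windows per 1000 whose CG number differs from the reference (top) and in 4mC level in CHH in percentage points (bottom); colours mark blocks differing by at least 10 windows per 1000. The 21 blocks with more mismatches in the mutant include the start of chromosome 4, and the 15 with more in wild type include 14 to 21 Mb of chromosome 8.

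Windows above background recurred in both libraries. In CHH 5243 windows passed in wild type and 3436 in the mutant, of 2150201 tested, and 926 were shared, against a mean of 8.69 and a maximum of 18 in circular shifts. Independence within strata of GC content and cytosine number would give 124. In CG 691 and 353 windows passed and 48 were shared, against 0.37 in shifts and 2.59 given composition. In CHG the numbers were 819, 286 and 47, against 0.5 and 2.28. The median GC content of the shared windows was 66% in CG, 65% in CHG and 64% in CHH, against 52%, 51% and 43% in the windows tested. For 5mC, 49625 windows passed in wild type and 83301 in the mutant, and 9213 were shared, against a mean of 2594 in shifts and 3068 given composition. The 5mC test used a single level per library although the level changed with read depth, so windows could pass by depth. Depth per CG was not among the strata, so the shared 5mC windows do not show recurrence apart from depth.

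The highest shared CHH window, at 11348901 to 11349000 of chromosome 6, had 26 of 42 cytosines called in wild type (61.9%, 45.6 to 76.4%) and 27 of 42 in the mutant (64.3%, 48.0 to 78.4%). The next, at 21910001 to 21910200 of chromosome 6, had 34 and 39 of 69, and a window at 19275301 to 19275400 of chromosome 3 had 24 and 27 of 56. At 9672501 to 9672600 of chromosome 1 the numbers were 19 and 7 of 25, at 14352201 to 14352300 of chromosome 8 they were 7 and 12 of 21, and at 23185301 to 23185400 of chromosome 1 they were 15 and 9 of 27. In CG the highest was 17802601 to 17802700 of chromosome 4, with 8 of 28 cytosines in wild type and 11 of 28 in the mutant. The region at 20896601 to 20896800 of chromosome 1 had 22 and 15 of 60 CG cytosines, and the same positions had 26 and 17 of 52 CHH cytosines called. The window at 26090401 to 26090500 of chromosome 2 ranked in CG, with 7 and 5 of 20, and in CHG, with 10 and 4 of 21. Other CG regions were 7611901 to 7612100 of chromosome 6 (16 and 13 of 50), 26600101 to 26600200 of chromosome 1 (6 and 7 of 23) and 20919901 to 20920000 of chromosome 5 (6 and 8 of 26). In CHG the highest was 13465601 to 13465700 of chromosome 3, with 9 and 7 of 21, followed among others by 8867801 to 8867900 of chromosome 1 (9 and 5 of 22) and 512701 to 512800 of chromosome 1 (8 and 4 of 20). The remaining CHG windows were 2686801 to 2686900 of chromosome 7 (5 and 6 of 21) and 20637301 to 20637400 of chromosome 4 (5 and 6 of 23). The GC content of these regions was between 61% and 73%.

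For 5mC the highest shared windows were not GC-rich. The window at 6263101 to 6263200 of chromosome V had 19 of 24 read calls modified in wild type (79.2%, 57.8 to 92.9%) and 16 of 28 in the mutant (57.1%, 37.2 to 75.5%). At 13297301 to 13297400 of chromosome 1 the numbers were 28 of 42 and 16 of 25, and at 7849801 to 7849900 of chromosome 7 they were 45 of 84 and 19 of 30. The others were 1803601 to 1803700 of chromosome 3 (39 of 90 and 14 of 21), 5450201 to 5450300 of chromosome 1 (32 of 57 and 25 of 48) and 11088201 to 11088300 of chromosome 7 (31 of 56 and 13 of 26). In these 6 windows no CG or CHG cytosine was called 4mC in either library.

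Few windows were called as differing between the libraries in 4mC, for which the Fisher exact test had little power in the simulations. It called 2 windows in CG, 0 in CHG and 7 in CHH, of 720257, 676386 and 2150201 tested. At an unadjusted p under 0.05 in this test there were 182, 254 and 1919 windows. The window at 19138801 to 19138900 of chromosome 4 was called in CG, with 22 of 27 cytosines in wild type and 0 of 27 in the mutant (Fisher exact test, adjusted p = 0.000149), and in CHH, with 23 and 1 of 29 (adjusted p = 0.00155). The CG window higher in the mutant lay at 2341101 to 2341200 of chromosome 6, with 0 and 19 of 29 (Fisher exact test, adjusted p = 0.0152). Neither window had 5mC calls in the mutant. The largest CHH differences in the other direction were at 589901 to 590000 of chromosome 8 (0 of 37 in wild type and 23 of 37 in the mutant, Fisher exact test, adjusted p = 0.00155) and 5823501 to 5823600 of chromosome 7 (0 and 19 of 35, adjusted p = 0.0458). Higher in wild type were also 15511401 to 15511500 of chromosome 8 (20 and 1 of 27, Fisher exact test, adjusted p = 0.0401) and 8578901 to 8579000 of chromosome 5 (25 and 0 of 38, adjusted p = 0.000297). A test conditional on the library-wide levels called 0 windows in each of the 4mC contexts.

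For 5mC 44776 of 1603099 windows differed, 40696 higher in the mutant and 4080 higher in wild type, without regard to depth or to the library-wide levels. A test conditional on those levels called 15869 higher in the mutant and 4160 higher in wild type. After the wild-type read calls were thinned to the number in the mutant, the numbers were 11719 and 1630. Thinning took modified and unmodified calls alike, so it kept the wild-type level. Neither test therefore removed the dependence of the level on read depth. The largest differences towards the mutant were at 6701001 to 6701100 of chromosome 2 (1 of 96 read calls in wild type and 18 of 21 in the mutant), 12940401 to 12940500 of chromosome 4 (0 of 100 and 17 of 22) and 2540701 to 2540800 of chromosome 2 (0 of 32 and 17 of 22). Towards wild type they were at 8202001 to 8202100 of chromosome 4 (16 of 23 and 1 of 22), 5797201 to 5797300 of chromosome 1 (21 of 35 and 0 of 45) and 10333901 to 10334000 of chromosome 6 (17 of 29 and 0 of 23).

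Coverage was uneven in both libraries. The coefficient of variation of window depth was 76.5% in wild type and 88.8% in the mutant, and the log2 depths correlated at r = 0.358 across 1778790 windows, which are not independent replicates. Of the windows with at least 4 CG cytosines, 2.21% in wild type and 6.39% in the mutant had no 5mC call. Long runs of at least 50 windows without calls in the mutant but with calls in wild type numbered 60, and 44 of them lay in the blocks with more mismatches in the mutant. The reverse was found in 22 runs, 18 of them in the blocks with more mismatches in wild type. Listed windows had a mean of at least 4 read calls per CG, and the mean depth was 10.8 in the mutant and 21.5 in wild type. The 2 numbers of runs were not compared at equal depth. The longest run by number of windows lay at 23865701 to 23891700 of chromosome 2, where 4 of 10976 cytosines were called 4mC in the mutant and 89 in wild type, at a wild-type depth of 27.5. Over all 60 runs the 4mC level was 0.163% in the mutant and 0.733% in wild type, and over the 22 runs it was 0.205% in wild type and 0.625% in the mutant.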

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

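The 5mC level on the 435 unplaced scaffolds was looked at because the comparisons did not use them and modified calls were present there. It was 2.60% in wild type (2.59 to 2.62%) and 2.39% in the mutant (2.37 to 2.41%), at a depth of 59.4 and 36 read calls per CG. In chromosomal windows of at least 35 read calls per CG the level in depth bins ran from 2.20% to 2.85% in wild type and from 2.17% to 2.85% in the mutant. The scaffolds and chromosomes were not compared at matched depth.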

How the results depend on the processing

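Matching on depth or GC content, the deposited mean fraction and the restriction to windows with 5mC calls in both libraries were chosen after the data were examined, and the other alternatives before. No paired analysis was possible because there was 1 library per genotype. Levels by annotated feature and by gene list were not run. No window held 50 CG or CHG cytosines, and thinning does not apply to 4mC, whose denominators were equal in both libraries. Of the values under alternatives fixed beforehand 51 stayed within the interval of the value or within 1.5 times the count, 35 moved further and 1 turned the sign of a difference whose interval excluded 0. Of those added later 1 stayed, 14 moved and 4 turned such a sign. The CG difference, whose interval included 0, is counted as moved although its sign also changed with at least 10 calls and in both sets of matched windows.

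The differences in level, mutant minus wild type in percentage points, changed most, and except for the matched windows the cause was not tested. As a mean of window levels they were 0.0292 in CG and -0.0686 in CHG for 4mC and 0.900 for 5mC. With at least 10 calls they were -0.0166 in CG and -0.115 in CHG, and with at least 50 calls -1.37 in CHH and 0.0510 for 5mC. For 4mC a call is a cytosine, so this CHH value rests on 898 cytosine-rich windows (interval -1.84 to -0.891), not on deeper coverage. Without windows above background the differences were 0.0159 in CG, -0.0721 in CHG and -0.0426 in CHH, and 5mC turned to -0.0741, a filter on the level itself that took out more windows above background in the mutant than in wild type. Without the windows with the most calls they were 0.0156 in CG and 0.50 for 5mC. In windows with 5mC calls in both libraries they were 0.0160 in CG, -0.0745 in CHG and -0.0380 in CHH. On the mean fraction they were 0.0313 in CG and -0.00873 in CHG, and CHH turned to 0.0274. At matched depth they were -0.0688 in CG, -0.0963 in CHG and -0.0378 in CHH, and 5mC turned to -0.0431. At matched depth and GC content they were -0.0374 in CG and -0.0379 in CHG, CHH turned to 0.0251 and 5mC to -0.0466.

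Shared windows above background numbered 96 in CG and 23 in CHG with at least 20 calls, 27 in CG at an adjusted p of 0.01, and 16 in CG, 330 in CHH and 847 for 5mC at a level of at least 0.2. Differing windows at an adjusted p of 0.01 numbered 1 in CG, 4 in CHH and 25327 for 5mC. The test with library-wide levels gave 0 in CG, 0 in CHH and 20029 for 5mC, thinning gave 13349 for 5mC, and at least 20 calls gave 1 in CHG. Relative to CHH, the wild-type ratio in CG was 0.354 as a mean of windows and 0.408 with at least 10 calls, and in CHG 0.642 without windows above background, 0.610 as a mean of windows and 0.660 with at least 10 calls. In the mutant it was 0.404 in CG as a mean of windows and 0.597 in CHG without windows above background. At matched depth and GC content the ratios were 0.421 in CG and 0.653 in CHG in wild type and 0.378 and 0.604 in the mutant, so the order of the libraries turned in CG. With at least 10 calls the ratio of V to the autosomes was 0.935 for CHG in the mutant and 1.45 for 5mC in wild type. Read depth is unknown behind each 4mC call, which limits every 4mC comparison.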

Other observations

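The tests in this part were chosen after the results were seen, except the comparison of context ratios, which was set before the data were examined, and the runs and copies named here were also picked after their values were seen. A repeated sequence of about 6 kb was found in some of the long runs that had 5mC calls in one library and none in the other. Its search templates were 12 of the 21 runs without any 4mC call in the library that lacked 5mC calls. Apart from these it matched 2 of the 9 other such runs and 14 of the 61 runs with a 4mC call. With each template set against the other templates, 14 of the 21 runs without a 4mC call matched. The templates were taken only from runs without 4mC calls, so a preference for such runs cannot be judged. Most runs, including the one with the most windows, at 23865701 to 23891700 of chromosome 2 (r = 0.365), did not match the repeated sequence. The 12 templates, chosen for a length of 5.9 to 6.1 kb, held 2529 to 2611 cytosines each, 10 of them missing in the mutant and 2 in wild type. Their profiles of CG, CHG and CHH numbers matched one another with a median best r of 0.991 and a lowest of 0.947, against a median of 0.213 for 200 random places of the genome. Of these random places 1 reached the limit of 0.5, with an r of 0.828. Examples missing in the mutant lay at 17402501 to 17408500 of chromosome 4 and 8473701 to 8479700 of chromosome 1, and the pair missing in wild type at 4415401 to 4421400 of chromosome 7 and 15718801 to 15724800 of chromosome 8.

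The genome held 437 places that matched this profile at an r of at least 0.5. Leaving out the 12 used for the search, 64 had 5mC calls in at most 10% of their windows in both libraries, 28 in the mutant only and 19 in wild type only, and the remaining 314 had calls in both. Of the 28, 11 held a 4mC call in the mutant, and of the 19, 7 held one in wild type. Of the 28 places, 10 lay in the blocks with more CG mismatches in the mutant and 0 in those with more in wild type. Of the 19 places, 14 lay in the blocks with more mismatches in wild type and 0 in those with more in the mutant. Of the 64 places, 40 lay in 48 blocks of the 183 alike in mismatches where both libraries had at least 110 mismatched windows per 1000, of which 20 are on chromosome 3 and 16 on chromosome 1, while 85 of all 425 places lay in those blocks.

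Stretches with 5mC calls in one library and few or none in the other are the pattern a biologist would most want to follow up. Of 82 long runs, 62 lay in blocks with more mismatches in the library that lacked calls. Over 218 circular shifts the mean was 7.01 and the highest value 58. Sequence that differs from the reference in segments of a library's genome is therefore a candidate explanation. Runs and mismatches both come from the number of CGs with 5mC calls, so a loss of calls alone could also bring them together. The difference in mismatches also correlated across blocks with windows lacking calls in the mutant only (Pearson r = 0.480) or in wild type only (-0.582). Ambiguous placement of reads among near-identical copies stays open. Of the 47 copies with few calls in a single library, 24 lay in that library's own mismatched blocks (mean 3.89 and highest value 21 over the shifts). Placement alone was not predicted to give this, but the limit of a shared measure applies here too. These copies also resembled the search templates more than copies with calls in both libraries did, with a median r of 0.954 against 0.898 (one-sided permutation p = 4.0e-05). That comparison is itself limited, because the templates were chosen among runs without calls. The 64 copies with few calls in both libraries had a median r of 0.967. Absence of the copy from the plants used was not tested, and 18 of the 47 held a 4mC call in the library with few 5mC calls. Whether the segments trace to the parents of the lines or to the mutation was not tested either. The part that the lower read depth of the mutant library has in its runs was also not tested.

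The higher 5mC level of the mutant library may come from its lower read depth. The difference was 0.421 points over all windows and -0.0431 points at matched depth. Native 5mC carried through amplification in the mutant, or an effect of genotype, was predicted to leave the mutant higher at matched depth and GC content. The difference there was -0.0466 points (-0.0618 to -0.0324). Each library was binned on its own depth, so the windows compared were not the same places. At 4 read calls per CG there were 10669 windows in wild type and 85426 in the mutant. The matched difference therefore cannot exclude either. Any other effect of genotype was not tested, since each genotype has 1 library.

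The variation of the 4mC difference along the genome may follow sequence that differs from the reference: between blocks with more mismatches in the mutant and those with more in wild type, the CG difference changed by 0.180 points (0.120 to 0.237), and the CHG and CHH contrasts were 0.195 and 0.227. The segments do not account for the genome-wide difference, since the 183 blocks alike in mismatches differed by -0.0882 points in CHG (-0.0952 to -0.0812) and -0.0639 in CHH (-0.0705 to -0.0577), against -0.0856 and -0.0613 over the genome, and at matched depth and GC content by -0.0422 (-0.0535 to -0.0312) and 0.0207 (0.0104 to 0.0319), against -0.0379 and 0.0251 over the genome. The CG contrast between the block classes remained, at 0.182 points (0.110 to 0.251), in windows matched on depth and GC content. Each library was binned on its own read calls per CG, so the windows compared were not the same places. The read depth behind a 4mC call is unknown, so this matching cannot exclude depth as a source of the contrast. Native 4mC carried through amplification in wild type was predicted to raise the CG and CHG ratios to CHH there. By the bound set before the data were examined the CG ratio, higher in the mutant by 0.0293 (0.0234 to 0.0352), argues against it. The CHG ratio had the predicted direction, with a difference of -0.0450 (-0.0502 to -0.0397). That bound took no account of depth: in wild type the CG level was 0.646% at 4 read calls and 0.396% at 20, with CHH at 1.11% and 1.09%. At matched depth and GC content, a test chosen afterwards, both ratios were lower in the mutant. The differences were -0.0429 (-0.0503 to -0.0348) in CG and -0.0485 (-0.0570 to -0.0402) in CHG. Carry-over and a difference in background therefore cannot be told apart.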
